A study of Mus musculus with 21 samples.

How the data were processed

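Glomeruli were isolated by laser microdissection from frozen kidney sections of 21 female mice aged 3 months, 1 library per mouse, and profiled by 3' tag RNA-seq (QuantSeq FWD, a kit that sequences the end of polyadenylated transcripts). The animals were mice with floxed Epac1 alleles and no Cre, called flox here, and littermates carrying a Cre recombinase that deletes Epac1 in podocytes, called cKO. Epac1 is encoded by Rapgef3. Nephritis was induced by intravenous nephrotoxic serum on 2 consecutive days and sampled on day 4 or day 11, and control mice received PBS. The groups held 3 flox PBS, 3 cKO PBS, 3 flox day 4, 4 cKO day 4, 4 flox day 11 and 4 cKO day 11 libraries.

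The deposited values were estimated counts of reads per gene, not normalized, per the file headers, with 1 table per library. Per the submitters' processing notes, FastQC, fastp, DRAGEN, Picard and the mm10 build were used, and no versions or roles are given there. Strand setting, treatment of duplicate reads, molecular identifiers and annotation release are not given in the sources used here. Of the values above 0, 95.2% were whole within 0.005. Overlapping and antisense genes, and near-identical copies such as the haemoglobin genes, are uncertain because the handling of shared reads is not stated. Each table held 35598 genes, of which 35513 (99.8%) were matched by identifier to a symbol in GENCODE M21 (GRCm38) and 85 were not, and 45 symbols were shared by several identifiers. Library totals ran from 4550550 to 24295712 reads with a median of 19470098, and 0 pairs of libraries held identical values. Floors of 3 counts cover counting error only.

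Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM factors, robust quasi-likelihood F test). All 21 libraries entered 1 model with 6 group means and 15 residual degrees of freedom, which left 13898 genes. TMM factors ran from 0.751 to 1.12, and the common biological coefficient of variation was 1.66. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with a standard error, the absolute fold change divided by the square root of F. A fold against a group without reads was computed against a floor of 3 counts over the group. The floor covers counting error in that group and not the spread between mice, so such a fold is a point value. CPM values are reads scaled by TMM-adjusted library size, and per-library log2 CPM used a prior count of 2. Unless another tool is named, each adjusted p is from this edgeR test or, for a gene list, from camera in limma 3.58.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

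The design, 11 comparisons, 28 gene lists of cell types and pathways drawn from general knowledge, and the rule for named genes were fixed before the data were examined. The comparisons were each nephritis stage against PBS within each genotype, the genotypes at each stage and on average, the genotype by nephritis interactions, and day 11 against day 4. The comparisons of day 4 and of day 11 with PBS averaged over genotypes, 2 in number, were added after the data were seen. The rule for named genes took the 8 called genes with the largest rise and the 8 with the largest fall at a mean log2 CPM of at least 3, without overlap between the groups in simple comparisons and passing over predicted genes. It also took up to 4 called members of each list with the smallest p, or the member with the smallest p where none was called, and every called gene where fewer than 10 were called. Rapgef3, Rapgef4, 5 podocyte genes (Nphs1, Podxl, Synpo, Wt1 and 1 not reported here) and, between genotypes, the glycolysis genes were always included. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the lists of a comparison. Proximal tubule content was the mean log2 CPM of its list per library, compared by exact two-sided permutation.

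Alternatives tried were DESeq2 1.42.0, limma voom with quality weights, models of the compared groups alone, an added minimum change of 1 on the log2 scale, median-ratio size factors, other low-count filters, a replicate block, a proximal tubule covariate, removal of mitochondrial and haemoglobin genes, and each library left out in turn. Chosen after seeing the data were removal of the ribosomal gene CT010467.1, a minimum mean log2 CPM of 6, removal of cKO day 4 replicate 3 (fewest genes detected) together with cKO day 11 replicate 3 (fewest reads), and a covariate for detected genes. The procedure was tested on simulated counts with the spread of these libraries. For cKO day 11 against cKO PBS, 11% of genes changed 4-fold and 2% of those changed 2-fold were recovered over 13667 genes. Of the 100 genes changed 4-fold there, 47 had a mean log2 CPM of at least 8, and all 11 recovered were among these. In the real data 471 of the 13898 tested genes had that level, so the shares given here overstate recovery for a typical gene. For cKO against flox at day 11 the shares were 39% and 1% over 13643 genes, and for flox day 4 against flox PBS 19% and 0% over 13639 genes. For day 11 against PBS averaged over genotypes they were 53% and 7% over 13668 genes. Of the 4-fold changes recovered, 37 of 39 between genotypes at day 11 and 50 of 53 in this averaged comparison had a mean log2 CPM of at least 8.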

Results

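Gene expression was measured in microdissected glomeruli of 21 mice, to examine the part played by podocyte Epac1 during the progression of glomerulonephritis. Epac1, encoded by Rapgef3, is an exchange factor for Rap GTPases that is activated by cyclic AMP. Library totals ran from 4550550 reads (cKO day 11 replicate 3) to 24295712 reads (flox day 4 replicate 1). The ribosomal RNA gene CT010467.1 (GRCm38 chromosome 17, 39846353 to 39848827, minus strand) took between 14.9% and 39.5% of the reads of a library, with group means of 29.0% ± 7.48 (SD, n = 4) at day 11 in cKO and 20.4% ± 6.85 (SD, n = 4) at day 11 in flox. Between 7871 and 13006 genes had at least 1 read. Over 14998 genes with a mean of at least 10 reads, the median Spearman correlation was 0.702 between libraries of the same group and 0.692 between libraries of different groups. Of the DESeq2 calls given beside the edgeR counts, 78.9% to 92.6% per comparison were genes for which a compared group had 0 reads.

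The targeted gene, Rapgef3 (ENSMUSG00000022469.17; GRCm38 chromosome 15, 97744770 to 97767972, minus strand), averaged 270.2 ± 60.5 CPM in flox PBS and 121 ± 50.1 CPM in cKO PBS (SD, n = 3 each). At day 4 the means were 191 ± 58.0 CPM in flox (SD, n = 3) and 119.9 ± 38.8 CPM in cKO (SD, n = 4). At day 11 they were 204.5 ± 100.7 CPM in flox and 176.9 ± 28.6 CPM in cKO (SD, n = 4 each). The log2 fold change of cKO against flox was −0.68 ± 0.25 (SE) on average over the stages, with a 95% interval of −1.19 to −0.18 that excludes 0, but the adjusted p over all genes was 0.55. By stage it was −1.16 ± 0.46 under PBS (adjusted p = 0.73), −0.67 ± 0.43 at day 4 (adjusted p = 0.88) and −0.21 ± 0.40 at day 11 (adjusted p = 1). The day 11 value turned to 0.17 without flox day 11 replicate 4. Tags at the 3' end can lie outside the deleted part, and glomeruli hold other cells that may keep the gene, so these values do not check the deletion. Rapgef4, which encodes the related Epac2, differed by 0.11 ± 0.63 (adjusted p = 1 by edgeR), and its sign turned under voom (−0.18).

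Between genotypes, averaged over PBS, day 4 and day 11, Nipal1, a member of the NIPA family of magnesium transporters, was the 1 gene called. Its log2 fold change was 7.12 ± 0.92 (SE, adjusted p = 0.00013). It averaged 151 ± 66.5 CPM in cKO PBS against 0.347 ± 0.144 in flox PBS, 69.0 ± 67.3 against 1.98 ± 1.66 at day 4, and 126 ± 111 against 0.683 ± 0.744 at day 11. Of the 11 cKO libraries 10 exceeded 20 CPM, the exception being cKO day 4 replicate 3 at 0.154 CPM, and 0 of the 10 flox libraries did. The call remained without each library in turn (adjusted p from 1.0e-06 to 0.0022). Prm1, a sperm protamine gene named after its values were seen, had reads in 11 of 11 cKO libraries and 0 of 10 flox libraries, at 23.8 ± 35.6, 27.8 ± 21.6 and 5.96 ± 5.68 CPM in cKO PBS, day 4 and day 11, but was not called (adjusted p = 0.10). At an unadjusted p under 0.05 there were 920 genes. Evenly spread p-values would give 695, but other splits of these libraries into groups of the same sizes gave a median of 918 genes. As many as 920 arose in 49 of 100 splits, the real one counted in, so this count shows no excess. DESeq2 called 933 genes and voom 3, and 0 of the 28 lists were called.

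The podocyte genes reported here were not called between the genotypes. On average over the stages the log2 fold changes of cKO against flox were −0.06 ± 0.20 for Nphs1, 0.05 ± 0.23 for Podxl, −0.05 ± 0.15 for Synpo and 0.27 ± 0.34 for Wt1 (SE, adjusted p = 1 for each). Leaving out single libraries turned the sign of Nphs1 (−0.14 to 0.05), Podxl (−0.12 to 0.19) and Synpo (−0.15 to 0.03).

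Glycolysis, named in the study's title, was examined as a list of 21 tested genes. The fixed list held 22, but the aldolase gene Aldoa was not matched by symbol and so was not tested. Averaged over the stages, 11 of the 21 were higher in cKO, the median log2 fold change was 0.06, and the list was not called (adjusted p = 0.99; the direction of the test turned without a low-count filter, with adjusted p = 0.98). The adjusted p was 0.78 under PBS, 0.97 at day 4, 0.89 at day 11, 0.86 for the interaction at day 4 and 0.67 for that at day 11. Counted as adjusted over the list alone, 0 members passed on average over the stages. For 7 of the 21 genes the 95% interval lay within a 2-fold change either way, among them Gapdh (−0.07, interval −0.79 to 0.65), Ldha (0.06, −0.60 to 0.71) and Pkm (−0.16, −0.63 to 0.31). Hk2, a hexokinase, had 0 reads in 4 cKO day 4 libraries against 20.6 ± 15.8 CPM (SD, n = 3) in flox, a log2 fold change of −9.03 against the floor (adjusted p = 0.66). Aldoc had 0 reads in flox PBS and reads in 1 of 3 cKO PBS libraries (adjusted p = 0.73), and its fold change was 0 without that library, cKO PBS replicate 3. Averaged over the stages, Hk2 was the 1 member whose 95% interval excludes 0 (−6.58 to −0.29, unadjusted p = 0.034), but this fitted interval is no bound. With the floor the average was −2.60, which rests on day 4, since Hk2 was at 0.0093 under PBS and higher in cKO at day 11 (1.21, with 12.2 ± 8.44 CPM against 5.28 ± 7.83 CPM, SD, n = 4 each). For the remaining members the interval reaches past a 2-fold change and includes 0.

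Within single stages edgeR called 0 genes between genotypes. Under PBS, Nipal1 was at 8.74 ± 1.76 (SE, adjusted p = 0.32), and 837 genes stood at an unadjusted p under 0.05, with 957 called by DESeq2 and 41 by voom. EdgeR called Nipal1 there with only the compared groups (adjusted p = 0.013), no low-count filter (0.0015) or without cKO day 4 and day 11 replicates 3 (0.036). At day 11 it did so with only the compared groups (7.49, adjusted p = 0.034), no low-count filter (0.00045) or detected genes as a covariate (0.034). Leaving out flox PBS replicate 3 gave 2 calls between genotypes under PBS. At day 4, 1031 genes stood at an unadjusted p under 0.05, DESeq2 called 833 and voom 8, and leaving out cKO day 4 replicate 1 gave 14 calls. The nuclear-encoded oxidative phosphorylation list was called higher in cKO at day 4 with a median log2 fold change of 0.11 (39 of 61 members higher, adjusted p = 0.021, and adjusted p = 0.97 with an estimated correlation). That call ended without flox day 4 replicate 2 (0.20), cKO day 4 replicate 2 (0.31) or cKO day 4 replicate 3 (0.41).

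At day 11, 4 lists were called between genotypes, and 0 of them held with an estimated correlation. The macrophage list was higher in cKO with a median log2 fold change of 0.65 (21 of 28 members higher, adjusted p = 0.0015, and adjusted p = 0.33 with an estimated correlation). The erythrocyte list was lower with a median of −1.26 (6 of 7 members lower, adjusted p = 0.0015, and adjusted p = 0.40 with an estimated correlation), and Hbb-bs, a haemoglobin gene, was at −2.29 ± 0.88 (SE, adjusted p = 0.84), and at −0.59 without flox day 11 replicate 1. Haemoglobin genes took 0.521% ± 0.671 of the reads in flox and 0.131% ± 0.066 in cKO (SD, n = 4 each). The matrix list was higher (29 of 34 members, median 0.52, adjusted p = 0.033) and the distal tubule list lower (15 of 19, median −0.46, adjusted p = 0.033). The matrix call ended without flox day 11 replicate 1 (0.27) or 2 (0.16) or cKO day 11 replicate 2 (0.53) or 4 (0.26). The distal tubule call ended without flox day 11 replicate 1 (0.71) or 2 (0.13) or cKO day 11 replicate 1 (0.13) or 2 (0.31). The macrophage call ended without cKO day 11 replicate 2 (0.11) and the erythrocyte call without flox day 11 replicate 1 (0.27). Single genes gave 0 calls by edgeR, 815 at an unadjusted p under 0.05, 531 by DESeq2 and 13 by voom, and 1 call without flox day 11 replicate 3.

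**Figure D1:**
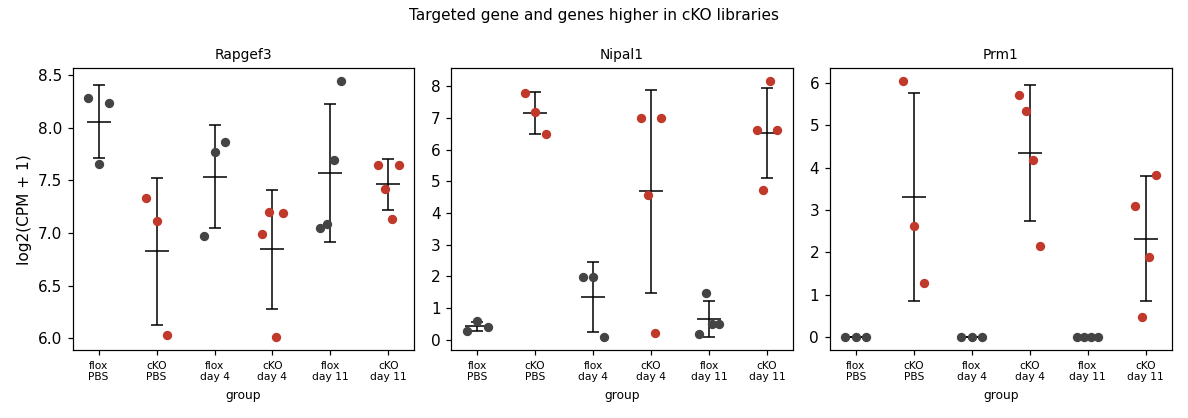
Log2(CPM + 1) of Rapgef3, Nipal1 and Prm1 in each library (points; grey, flox; red, cKO) by group, with the group mean (horizontal bar) and SD (error bar). Nipal1 exceeded 20 CPM in 10 of 11 cKO libraries and 0 of 10 flox libraries, and Prm1 had reads in 11 and 0 of them.

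In flox mice, the cell cycle list was higher 4 days after serum than under PBS. Of 38 list members 35 were higher, with a median log2 fold change of 2.86 when genes without reads in a group were set to the floor (adjusted p = 1.1e-11, and adjusted p = 0.13 with an estimated correlation). Mcm5, a subunit of the replicative helicase, had 0 reads in the PBS group and 31.8 ± 35.5 CPM at day 4 (SD, n = 3), a log2 change of at least 9.19 (adjusted p = 0.47), and 2 members passed when adjusted over the list alone. The podocyte list was lower (23 of 34 members, median −0.28, adjusted p = 0.012, and adjusted p = 0.62 with an estimated correlation), led by Thsd7a, a membrane protein of podocyte foot processes, at −1.50 ± 0.31 (SE, adjusted p = 0.27). That list call ended without flox PBS replicate 1 (0.051) or 3 (0.071). The mitochondrially encoded list (13 of 13 members above 0, median 0.43, adjusted p = 0.025) and the immediate early and heat shock list (19 of 25, median 0.67, adjusted p = 0.036) were higher, each at an adjusted p of 0.62 with an estimated correlation. The mitochondrial call ended without flox PBS replicate 1 (0.069) or 3 (0.091) or flox day 4 replicate 1 (0.086) or 2 (0.054). The immediate early call ended without flox PBS replicate 1 (0.069), 2 (0.053) or 3 (0.071) or flox day 4 replicate 2 (0.061) or 3 (0.0645). The immediate early list was called higher in 6 of 13 comparisons, those of day 4 and of day 11 with PBS, with medians of 0.87 in flox at day 11 and 0.52 in cKO at day 4, and none of the 6 calls held with an estimated correlation (adjusted p from 0.061 to 0.62). Spp1 was at 1.43 ± 0.47 and Acta2 at 1.15 ± 0.42 (SE), neither called. Single genes gave 0 calls by edgeR, 1102 at an unadjusted p under 0.05, 1162 by DESeq2 and 62 by voom, with 3 calls without flox PBS replicate 3 and 1 without flox day 4 replicate 2.

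At day 11 in flox mice, the extracellular matrix and cell cycle lists were higher than under PBS. The matrix list had 31 of 34 members above 0 and a median log2 fold change of 1.29 (adjusted p = 1.3e-09, and adjusted p = 0.12 with an estimated correlation), and 7 members passed when adjusted over the list alone, Sparc, Spp1 and Acta2 among them. Sparc, a collagen-binding matricellular protein, went from 2901 ± 617 to 5876 ± 575 CPM, and Spp1 (osteopontin) from 62.3 ± 13.9 to 285 ± 85.1 CPM (SD, n = 3 and 4), log2 changes of 1.02 ± 0.21 and 2.19 ± 0.46 (SE). The cell cycle list had 34 of 38 members above 0 (median 3.29, adjusted p = 3.4e-10, and adjusted p = 0.12 with an estimated correlation), and Mcm5 was at 9.30 on the log2 scale against the floor (adjusted p = 0.25). Flox day 11 replicate 1 stood apart with a mean log2 CPM of −0.44 for the cell cycle list, within the range of flox PBS (−1.31 to −0.24), against 3.08 to 3.37 in the other 3 libraries. This library had 9933 detected genes, the fewest of its group. The podocyte list was lower (20 of 34 members, median −0.18, adjusted p = 0.010, and adjusted p = 0.47 with an estimated correlation), with Thsd7a at −1.53 ± 0.29 (SE, adjusted p = 0.11). This call ended without flox PBS replicate 3 (0.12), flox day 11 replicate 2 (0.098) or flox day 11 replicate 3 (0.16). Col4a1 and Acta2 stood at 0.95 ± 0.26 and 1.11 ± 0.40 (SE), neither called. EdgeR called 0 single genes, with 1147 at an unadjusted p under 0.05, 1176 by DESeq2, 26 by voom and 3 without flox PBS replicate 3.

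In cKO mice at day 4, the oxidative phosphorylation, cell cycle and matrix lists were called higher than under PBS, but not every library followed. The nuclear-encoded oxidative phosphorylation list had 47 of 61 members higher with a median log2 fold change of 0.42 (adjusted p = 3.3e-08, and adjusted p = 0.19 with an estimated correlation), and its leading member Atp5f1, a subunit of ATP synthase, was at 1.80 ± 0.64 (SE, adjusted p = 0.60), and at 0.94 without cKO day 4 replicate 3. The cell cycle list had 27 of 38 members higher (median 1.80, adjusted p = 9.7e-06, and adjusted p = 0.25 with an estimated correlation) and the matrix list 25 of 34 (median 0.62, adjusted p = 0.0013, and adjusted p = 0.38 with an estimated correlation). By mean log2 CPM of the matrix list, day 4 replicates 2 and 3 (3.42 and 2.91) lay below the PBS libraries (4.24 to 4.64) and replicates 1 and 4 (5.91 and 5.04) above them. For the cell cycle list replicate 3 (−0.75) lay below the PBS libraries (−0.35 to 1.74). Thsd7a was at −1.18 ± 0.29, Acta2 at 1.32 ± 0.40 and Col4a2, a basement membrane collagen, at 1.12 ± 0.34 (SE, adjusted p = 0.60 for each). Spp1 averaged 78.9 ± 24.1 CPM against 71.1 ± 25.5 CPM under PBS (SD, n = 4 and 3). Single genes gave 0 calls by edgeR, 1134 at an unadjusted p under 0.05, 834 by DESeq2 and 36 by voom, and 10 without cKO day 4 replicate 1.

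At day 11 in cKO mice, 7 genes were called against PBS, 6 higher and 1 lower. Thsd7a fell from 1168 ± 110 to 279 ± 103 CPM (SD, n = 3 and 4), a log2 fold change of −2.07 ± 0.29 (SE, adjusted p = 0.00064). Col4a1, a basement membrane collagen, rose by 1.76 ± 0.27 (adjusted p = 0.0016) and Sparc by 1.43 ± 0.22 (adjusted p = 0.0016), and these 3 calls held without each library. The actin-binding tropomyosin gene Tpm1 rose by 1.66 ± 0.29 (adjusted p = 0.0084), Csrp1 by 1.55 ± 0.26 (adjusted p = 0.0061), Spp1 by 2.38 ± 0.47 (adjusted p = 0.036) and the calcium-binding S100a6 by 2.45 ± 0.49 (adjusted p = 0.045). Acta2, smooth muscle actin, was at 1.67 ± 0.40 (adjusted p = 0.30) and Synpo at −0.71 ± 0.27 (adjusted p = 0.81). Calls were lost without cKO PBS replicate 1 (S100a6 0.64, Spp1 0.53, Csrp1 0.066), 2 (S100a6 0.54, Spp1 0.15, Tpm1 0.15, Csrp1 0.15) and 3 (S100a6 0.054, Spp1 0.27, Tpm1 0.14). The same held for cKO day 11 replicate 1 (S100a6 0.090, Spp1 0.054), 2 (S100a6 0.27, Spp1 0.27, Tpm1 0.055) and 4 (S100a6 0.12, Spp1 0.15), and the number called fell to 4, 3 and 4 without cKO PBS replicate 1, cKO PBS replicate 2 and cKO day 11 replicate 2. With the proximal tubule covariate S100a6 (2.41, adjusted p = 0.20) and Spp1 (2.44, adjusted p = 0.089) lost their calls, as did Spp1 with the replicate block (adjusted p = 0.12) and S100a6 over genes with a mean log2 CPM of at least 6 (adjusted p = 0.051).

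Of the lists, 13 were called at day 11 in cKO, a call being for the list and not for each member. The extracellular matrix list was higher, with 33 of 34 members above 0 (median log2 fold change 1.68, adjusted p = 3.1e-22), of which 3 were called and 11 passed when adjusted over the list alone. The cell cycle list was higher (33 of 38 members above 0, median 1.90, adjusted p = 6.9e-12, with Stmn1 at 2.21 ± 0.79, not called), as were the macrophage (22 of 28, median 1.002, adjusted p = 8.2e-08) and basement membrane lists (13 of 16, median 0.24, adjusted p = 0.00050). The lists of chemokines and adhesion (median 0.90, adjusted p = 0.00029) and of parietal cell activation and crescents (median 0.84, adjusted p = 0.00029) were higher as well. The erythrocyte list was lower (7 of 7 members below 0, median −2.38, adjusted p = 9.6e-10, with Hbb-bs at −3.39 ± 0.95, not called), as was the distal tubule list (15 of 19, median −0.94, adjusted p = 4.2e-07, with Slc12a1 at −2.12 ± 0.66, not called). Slc12a1 was called without cKO day 11 replicate 3 (−3.15, adjusted p = 0.022). The 8 lists named so far kept their calls with an estimated correlation. The podocyte list was lower with 25 of 34 members (median −0.63, adjusted p = 3.5e-05, and adjusted p = 0.089 with an estimated correlation), and the mitochondrially encoded list with 12 of 13 (median −0.51, adjusted p = 2.9e-05, adjusted p = 0.25 with an estimated correlation, and 0.081 with a proximal tubule covariate; mt-Nd3 −1.23 ± 0.41). The proximal tubule list was lower (21 of 23, median −0.67, adjusted p = 0.00050, adjusted p = 0.31 with an estimated correlation and 0.12 without cKO PBS replicate 3). The parietal epithelial list (15 of 18, median 1.16, adjusted p = 0.00031, and adjusted p = 0.052 with an estimated correlation) and the immediate early and heat shock list (18 of 25, median 0.65, adjusted p = 8.6e-05, and adjusted p = 0.064 with an estimated correlation) were higher. The CT010467.1 share was 21.6% ± 4.09 under PBS and 29.0% ± 7.48 at day 11 (SD). Library totals averaged 20.5 ± 0.54 and 12.4 ± 5.79 in units of 1e6 reads (SD, n = 3 and 4). Haemoglobin genes took 1.10% ± 0.79 of reads under PBS (SD, n = 3) and 0.131% ± 0.066 at day 11 (SD, n = 4).

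**Figure D2:**
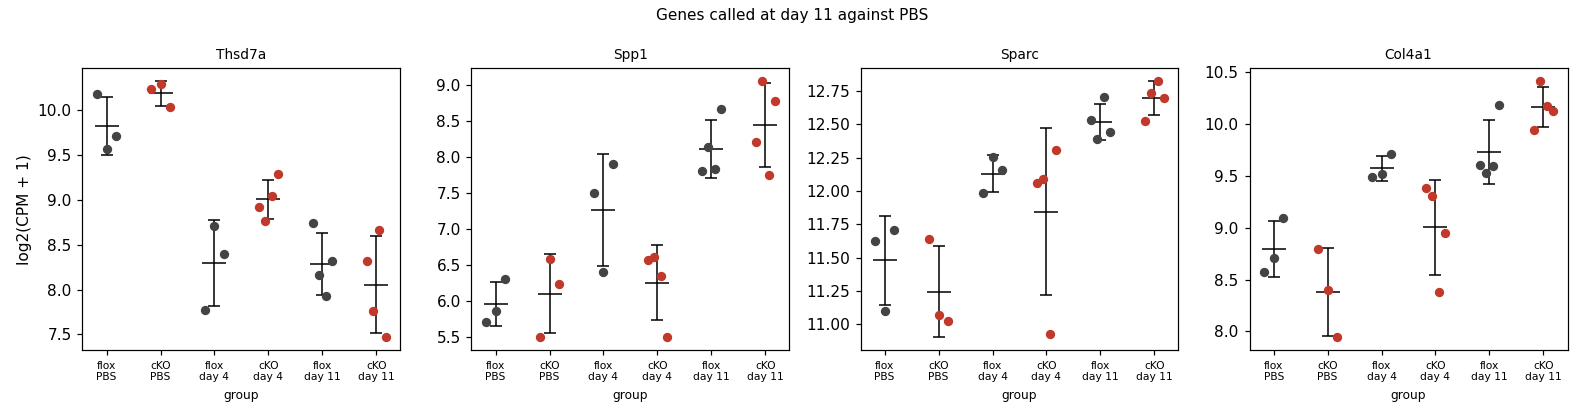
Log2(CPM + 1) of Thsd7a, Spp1, Sparc and Col4a1 in each library (points; grey, flox; red, cKO) by group, with the group mean (horizontal bar) and SD (error bar). Thsd7a averaged 918 CPM in flox PBS and 318 CPM in flox day 11, and 1168 CPM in cKO PBS and 279 CPM in cKO day 11.

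Averaging the genotypes, a comparison chosen after the data were seen, gave 17 called genes at day 11 against PBS, 16 higher and 1 lower. Thsd7a was lower, at −1.80 ± 0.20 (SE, adjusted p = 6.8e-06). Matrix and basement membrane genes were higher, with Spp1 at 2.29 ± 0.33 (adjusted p = 0.00027), Sparc at 1.22 ± 0.15 (adjusted p = 2.8e-05), Col4a1 at 1.35 ± 0.19 (adjusted p = 0.00023), and Col4a2 at 1.17 ± 0.24 (adjusted p = 0.032), and S100a6 was at 2.25 ± 0.35 (adjusted p = 0.00062). Tpm1 (1.31 ± 0.20) and Acta2 (1.39 ± 0.28) of the contractile cytoskeleton were higher, as were Actb (0.78 ± 0.12), Flna (1.22 ± 0.23), Cald1 (0.90 ± 0.16), Tpm4 (1.10 ± 0.21) and Csrp1 (1.05 ± 0.18), these 5 named after their values were seen. Tnfaip2, a gene induced by tumour necrosis factor, was at 2.03 ± 0.36, the chaperone gene Clu at 1.51 ± 0.32 and Akap12 at 1.27 ± 0.27. Pet117 had 0 reads under PBS in both genotypes and 6.83 ± 13.7 CPM in flox and 58.3 ± 31.1 CPM in cKO at day 11 (SD, n = 4 each), a log2 change of 8.60 against the floor (adjusted p = 0.047). At an unadjusted p under 0.05 there were 1267 genes, and DESeq2 called 1194 and voom 90. Without single libraries the calls of Acta2, Col4a2, Akap12 and Clu were lost in 8, 8, 9 and 10 of 14 cases (highest adjusted p 0.14, 0.13, 0.15 and 0.14). Pet117 was lost in 11 of 14 (adjusted p = 1 without flox day 11 replicate 2), Tpm4 without cKO PBS replicate 2 (0.051) and Cald1 under voom (0.33). With the proximal tubule covariate the calls of Acta2 (0.17), Col4a2 (0.15), Akap12 (0.28) and Tpm4 (0.084) were lost. With the replicate block the losses were Acta2 (0.19), Col4a2 (0.11), Akap12 (0.11), Tpm4 (0.064), Clu (0.24), Flna (0.089) and Pet117 (0.11).

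Among podocyte genes at day 11 averaged over genotypes, the list was lower with 26 of 34 members (median −0.48, adjusted p = 4.9e-06, and adjusted p = 0.061 with an estimated correlation), and 8 members passed when adjusted over the list alone. Synpo was at −0.56 ± 0.19 (SE, adjusted p = 0.34) and Wt1 at −1.01 ± 0.41 (adjusted p = 0.39), neither called. The matrix list was higher, with 33 of 34 members above 0 (median 1.57, adjusted p = 8.5e-25; 4 called and 15 when adjusted over the list alone), as was the cell cycle list with 35 of 38 (median 2.41, adjusted p = 1.6e-19; 11 when adjusted over the list alone). The macrophage (median 0.95, adjusted p = 4.3e-05), parietal epithelial (median 1.16, adjusted p = 5.4e-05) and basement membrane lists (median 0.39, adjusted p = 0.00074) were higher, and the distal tubule list was lower (median −0.65, adjusted p = 2.8e-05). These 6 lists held with an estimated correlation. The proximal tubule list was lower (22 of 23, median −0.56, adjusted p = 5.0e-06, and adjusted p = 0.13 with an estimated correlation). Over all comparisons 66 list calls were made, and 19 held with an estimated correlation. Apart from the 6 just named and the 8 at day 11 in cKO, those were 5 lists between day 11 and day 4.

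At day 4 averaged over genotypes, again chosen after the data were seen, 3 genes were called. The tubulin gene Tuba1b rose by 1.23 ± 0.18 (SE, adjusted p = 0.0024) and Tpm4 by 1.21 ± 0.21 (adjusted p = 0.012), and Thsd7a was lower at −1.34 ± 0.21 (adjusted p = 0.0033). Acta2 was at 1.23 (adjusted p = 0.18). The cell cycle list was higher, with 33 of 38 members above 0 (median 2.12, adjusted p = 7.6e-15, and adjusted p = 0.055 with an estimated correlation), 9 of them passing when adjusted over the list alone, as was the oxidative phosphorylation list with 53 of 61 (median 0.38, adjusted p = 2.6e-06, and adjusted p = 0.31 with an estimated correlation). At an unadjusted p under 0.05 there were 1290 genes, and DESeq2 called 1298 and voom 16. The Tpm4 call was lost without flox PBS replicate 1 (0.062) or cKO PBS replicate 2 (0.086), under voom (0.051) and with the replicate block (0.061). The count rose to 6, 5, 12 and 16 without flox PBS replicate 3, cKO PBS replicate 3, cKO day 4 replicate 1 and cKO day 4 replicate 3.

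Between the stages, averaged over genotypes, the mitochondrial and tubule lists were lower and the matrix list higher at day 11 than at day 4. All 13 mitochondrially encoded genes were below 0 (median log2 fold change −0.68, adjusted p = 5.0e-17), 11 of them when adjusted over the list alone, with mt-Atp6 at −0.71 ± 0.15 (SE, adjusted p = 0.16). The nuclear-encoded oxidative phosphorylation list was lower, with 55 of 61 members below 0 (median −0.53, adjusted p = 4.9e-14; Atp5b −1.001 ± 0.25), as were the proximal tubule list with 22 of 23 (median −0.87, adjusted p = 5.0e-12; Kap −3.24 ± 0.85, and −2.35 without cKO day 4 replicate 3) and the distal tubule list with 17 of 19 (median −1.25, adjusted p = 5.5e-09; Umod −1.27 ± 0.30). The matrix list was higher with 32 of 34 above 0 (median 0.80, adjusted p = 8.6e-11; Spp1 1.497 ± 0.30). None of the genes named here was called. These 5 lists kept their calls with an estimated correlation and without each library. Mitochondrial genes took 7.68% ± 0.37 (flox, n = 3) and 7.77% ± 1.88 (cKO, n = 4) of reads at day 4 and 5.47% ± 2.23 (flox, n = 4) and 3.90% ± 0.46 (cKO, n = 4) at day 11 (SD). Under PBS the share was 5.57% ± 0.44 in flox and 6.39% ± 1.09 in cKO (SD, n = 3 each). In flox the mean at day 11 was thus near that under PBS, and in cKO it was below it. Single genes gave 0 calls by edgeR, 1191 at an unadjusted p under 0.05, 1025 by DESeq2 and 11 by voom, and 6, 4 and 1 calls without cKO day 4 replicate 1, flox day 11 replicate 1 and cKO day 11 replicate 3.

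**Figure D3:**
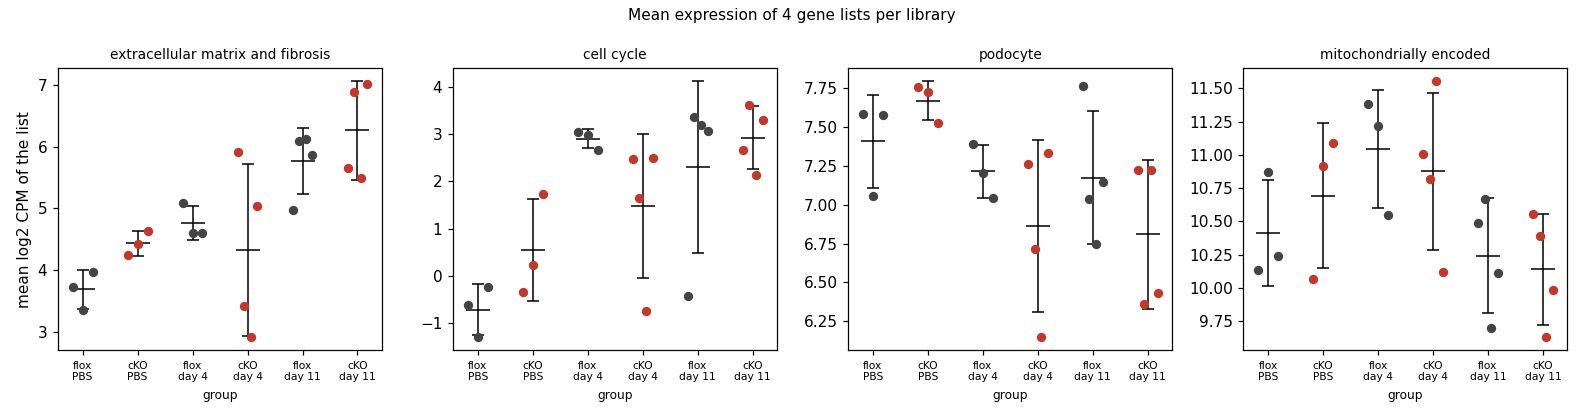
Mean log2 CPM of the extracellular matrix, cell cycle, podocyte and mitochondrially encoded lists in each library (points; grey, flox; red, cKO) by group, with the group mean (horizontal bar) and SD (error bar). Against PBS at day 11 in cKO, matrix genes had a median log2 fold change of 1.68 and podocyte genes of −0.63.

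Whether the response to serum differed between genotypes was tested with interaction terms. At day 4 edgeR called 0 genes, with 1076 at an unadjusted p under 0.05, 1161 by DESeq2, 10 by voom and 4 without cKO day 4 replicate 1. Hk2 stood at −9.04 against the floor (adjusted p = 0.54) and Rapgef3 at 0.49 ± 0.63 (SE). At day 11 edgeR called 0 genes, with 964 at an unadjusted p under 0.05, 1003 by DESeq2 and 4 by voom. Apoe, a lipoprotein gene, was at 1.39 ± 0.47, Hbb-bs at −3.06 ± 1.32 (adjusted p = 0.68; −1.36 without flox day 11 replicate 1 and −4.35 without flox PBS replicate 3) and Rapgef3 at 0.95 ± 0.61 (SE, adjusted p = 0.91). The erythrocyte list was lower in the day 11 interaction with 7 of 7 members (median −2.84, adjusted p = 0.0015, and adjusted p = 0.81 with an estimated correlation), and this ended without cKO PBS replicate 1 (0.060) or flox day 11 replicate 1 (0.076). The median of all genes lay at −0.28 at day 4 and −0.20 at day 11 in these terms, and at −0.15 and −0.11 with median-ratio factors.

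Across genes, which are not independent replicates, the log2 fold changes of the genotypes, each against its own PBS group, had a Pearson correlation of 0.046 (Spearman 0.046) at day 4 and 0.053 (0.054) at day 11 over 13898 genes. Over the 471 genes with a mean log2 CPM of at least 8 the Pearson values were 0.50 and 0.55.

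Proximal tubule content, a measure of neighbouring tissue in the dissected material, was compared in 7 group pairs, not including day 11 against day 4, by a test in which no single pair could pass. The proximal tubule list was called lower at day 11 than under PBS in flox (21 of 23 members lower, median −0.45, adjusted p = 0.00082, and adjusted p = 0.47 with an estimated correlation) and in cKO, in both averaged, and against day 4. The flox call ended without flox PBS replicate 2 (0.081) or flox day 11 replicate 3 (0.16). Content as mean log2 CPM was 5.92 ± 0.68 in flox PBS, 6.38 ± 0.91 in cKO PBS, 6.40 ± 0.79 and 6.24 ± 0.50 at day 4 in flox and cKO, and 5.31 ± 0.995 and 5.59 ± 0.53 at day 11 (SD). By exact two-sided permutation the adjusted p was 0.80 in each of the 7 comparisons, and the smallest possible p before adjustment is 0.10 with 3 mice against 3 and 0.029 in the other pairs, so this decides nothing about tissue content.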

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

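Single libraries lying apart from the others of their group were sought in groups of 4 with Dixon's test, ignoring groups whose whole range was 0.05 or less on the log2 scale. Of 195 sets of group values 20 had such a library, and no explanation of them was tested. The nominal rate of 5% holds for independent, normally distributed values. These sets share the same libraries and some hold values at 0 reads, so no excess over chance can be read from the count. Values are log2 CPM, with −3.16 standing for 0 reads.

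In cKO day 4 replicate 3, the library with the fewest detected genes, Atp5f1 was at 9.20 (other 3 libraries 6.95 to 7.28), Aldoc at 6.26 (−3.16 to −2.66), Rapgef4 at −3.16 (5.60 to 7.11), Tuba1b at 9.30 (10.05 to 10.18) and Flna at 8.46 (9.62 to 9.84). In cKO day 4 replicate 2, Wt1 was at 4.21 (6.96 to 7.23). In flox day 11 replicate 3, Atp5f1 was at 4.76 (6.98 to 7.41), mt-Nd3 at 6.74 (9.31 to 9.78) and the basement membrane list at 5.99 (6.42 to 6.51). In flox day 11 replicate 1, the cell cycle list was at −0.44 (3.08 to 3.37), the parietal epithelial list at 1.18 (3.57 to 4.02) and the chemokine list at 1.23 (2.98 to 3.17).

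In flox day 11 replicate 4, Col4a1 was at 10.19 (9.53 to 9.60) and Flna at 10.06 (9.50 to 9.55). In flox day 11 replicate 2, Pet117 was at 4.78 and at −3.16 in the other libraries. In cKO day 11 replicate 2, Akap12 was at 9.09 (8.50 to 8.57) and Apoe at 8.64 (8.31 to 8.34). In cKO day 11 replicate 3, the library with the fewest reads, Hk2 was at −3.16 (3.75 to 4.21) and the immediate early list at 3.51 (4.60 to 4.81). In cKO day 11 replicate 4, Aldoc was at 3.46 and at −3.16 in the other libraries.

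A difference between genotypes in the response at day 11 was found for the erythrocyte list (adjusted p = 0.0015 in the interaction), which was lost with an estimated correlation (adjusted p = 0.81).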

How the results depend on the processing

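Choices added after seeing the data were the removal of CT010467.1, the minimum mean log2 CPM of 6, the removal of the library with the fewest genes detected and that with the fewest reads, and the covariate for detected genes. Of 28 gene calls, 28 were kept with DESeq2, with median-ratio factors, with no low-count filter, with a CPM of at least 5 in 3 libraries, without mitochondrial and haemoglobin genes, without CT010467.1 and without the libraries of fewest genes and reads, 26 with voom, 25 of 27 with only the compared groups, 22 with the proximal tubule covariate, 19 with the replicate block, 27 with detected genes as a covariate, 25 of the 26 still tested at a mean log2 CPM of at least 6, and 17 without any 1 library. 0 reversed. Of 66 list calls, 66 were kept with median-ratio factors and without CT010467.1, 55 of 55 without mitochondrial and haemoglobin genes, 65 with no low-count filter, 64 with a CPM of at least 5 in 3 libraries, 61 with the replicate block, 60 without the libraries of fewest genes and reads, 58 with detected genes as a covariate, 55 with the proximal tubule covariate, 43 of 58 at a mean log2 CPM of at least 6, 19 with an estimated correlation and 46 without any 1 library. New list calls numbered 2 with median-ratio factors, 11 with no low-count filter, 1 with the block, 7 with the tubule covariate, 7 at a mean log2 CPM of at least 6, 7 without the libraries of fewest genes and reads and 7 with detected genes as a covariate. Adding a minimum change of 1 on the log2 scale moved no count by over 1.5 times. Models of the compared groups alone gave no value for the genotypes on average, which use all groups. The spread between libraries of a group, not read depth alone, bounds what was detectable. With 1 library per mouse, differences between mice and technical loss cannot be told apart in it. In simulated data with that spread 2% of 2-fold changes were recovered for cKO day 11 against PBS over 13667 genes, with highly expressed genes over-represented among the changed ones. The cause of each change below was not tested unless the alternative tests fewer genes or fewer libraries.

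No pairing by the numbers shared between groups was seen. The 48 pairs with the same number in different groups had correlations of −0.070 to 0.061, 0 of them over 0.1, and 5 of 21 libraries correlated best with their own number. A weak shared effect could be missed, since even libraries of the same group were hardly more alike (median Spearman 0.702) than those of different groups (0.692). With the replicate block the number called was 10 against 17 for averaged day 11, 6 against 7 for cKO day 11 and 2 against 3 for averaged day 4.

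With DESeq2 the number called was 1162 for flox day 4, 1176 for flox day 11, 834 for cKO day 4, 670 for cKO day 11, 957 for genotypes under PBS, 833 for genotypes at day 4, 531 for genotypes at day 11, 933 for genotypes on average, 1161 for interaction at day 4, 1003 for interaction at day 11, 1025 for day 11 against day 4, 1298 for averaged day 4 and 1194 for averaged day 11. With voom and quality weights the number called was 62 for flox day 4, 26 for flox day 11, 36 for cKO day 4, 103 for cKO day 11, 41 for genotypes under PBS, 8 for genotypes at day 4, 13 for genotypes at day 11, 3 for genotypes on average, 10 for interaction at day 4, 4 for interaction at day 11, 11 for day 11 against day 4, 16 for averaged day 4 and 90 for averaged day 11. With no low-count filter the number called was 2 for flox day 4, 4 for flox day 11, 1 for cKO day 4, 12 for cKO day 11, 1 for genotypes under PBS, 2 for genotypes at day 4, 1 for genotypes at day 11, 3 for genotypes on average, 4 for day 11 against day 4, 17 for averaged day 4 and 39 for averaged day 11. Over genes with a mean log2 CPM of at least 6 the number called was 1 for flox day 4, 0 for genotypes on average and 27 for averaged day 11. Without both cKO day 4 replicate 3 and cKO day 11 replicate 3 the number called was 1 for flox day 4, 6 for flox day 11, 13 for cKO day 11, 1 for genotypes under PBS, 2 for day 11 against day 4, 17 for averaged day 4 and 37 for averaged day 11. With only the compared groups in the model the number called was 1 for genotypes under PBS, 1 for genotypes at day 11 and 27 for averaged day 11. With detected genes as a covariate the number called was 1 for genotypes at day 11 and 6 for averaged day 4.

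With no low-count filter the adjusted p of called lists that lost their call was for cKO day 4 immediate early 0.0977. Over genes with a mean log2 CPM of at least 6 the adjusted p of called lists that lost their call was for flox day 4 immediate early 0.434, for flox day 11 immediate early 0.511, for cKO day 4 macrophage 0.0721, mitochondrially encoded 0.0654, cell cycle 0.142 and immediate early 0.390, for cKO day 11 chemokine 0.0518 and crescent 0.0614, for genotypes at day 4 oxidative phosphorylation 0.236, for genotypes at day 11 distal tubule 0.0767, for day 11 against day 4 fatty acid oxidation 0.156, for averaged day 4 macrophage 0.0956 and immediate early 0.322, for averaged day 11 chemokine 0.483 and crescent 0.102. Without both cKO day 4 replicate 3 and cKO day 11 replicate 3 the adjusted p of called lists that lost their call was for cKO day 4 mitochondrially encoded 0.185, immediate early 0.0696 and Nrf2 0.205, for genotypes at day 4 oxidative phosphorylation 0.458, for day 11 against day 4 Nrf2 0.129, for averaged day 4 Nrf2 0.169. With the replicate number as a block the adjusted p of called lists that lost their call was for flox day 4 immediate early 0.0532, for flox day 11 parietal epithelial 0.103 and immediate early 0.140, for cKO day 4 immediate early 0.0788, for genotypes at day 11 distal tubule 0.0509. With detected genes as a covariate the adjusted p of called lists that lost their call was for flox day 4 podocyte 0.120 and immediate early 0.0772, for flox day 11 podocyte 0.158, parietal epithelial 0.101 and immediate early 0.129, for cKO day 4 mitochondrially encoded 0.168 and Nrf2 0.0970, for genotypes at day 4 oxidative phosphorylation 0.196. With an estimated correlation the adjusted p of called lists that lost their call was for flox day 4 podocyte 0.618, mitochondrially encoded 0.618, cell cycle 0.130 and immediate early 0.618, for flox day 11 podocyte 0.474, parietal epithelial 0.474, proximal tubule 0.474, matrix 0.124, cell cycle 0.124 and immediate early 0.474, for cKO day 4 macrophage 0.185, oxidative phosphorylation 0.185, mitochondrially encoded 0.595, matrix 0.380, cell cycle 0.252, immediate early 0.462 and Nrf2 0.185, for cKO day 11 podocyte 0.0890, parietal epithelial 0.0521, proximal tubule 0.306, mitochondrially encoded 0.252 and immediate early 0.0641, for genotypes at day 4 oxidative phosphorylation 0.975, for genotypes at day 11 distal tubule 0.614, macrophage 0.329, erythrocyte 0.402 and matrix 0.8292, for interaction at day 11 erythrocyte 0.807, for day 11 against day 4 erythrocyte 0.252, TCA cycle 0.0706, fatty acid oxidation 0.0639 and Nrf2 0.0639, for averaged day 4 podocyte 0.359, macrophage 0.314, oxidative phosphorylation 0.314, mitochondrially encoded 0.359, matrix 0.314, cell cycle 0.0554, immediate early 0.314 and Nrf2 0.314, for averaged day 11 podocyte 0.0608, proximal tubule 0.128, erythrocyte 0.0608, mitochondrially encoded 0.292, chemokine 0.115, immediate early 0.0608 and crescent 0.0848. With the proximal tubule covariate the adjusted p of called lists that lost their call was for flox day 4 mitochondrially encoded 0.192, for flox day 11 parietal epithelial 0.0782, proximal tubule 0.292 and immediate early 0.0870, for cKO day 4 immediate early 0.0629, for cKO day 11 proximal tubule 0.8291 and mitochondrially encoded 0.0813, for day 11 against day 4 TCA cycle 0.0849 and fatty acid oxidation 0.133, for averaged day 11 proximal tubule 0.252 and mitochondrially encoded 0.240. The covariate is the mean of the proximal tubule list itself, so the losses of that list are largely built in and test nothing about it. They are included in the number of list calls lost with the covariate given above. With a CPM of at least 5 in 3 libraries the adjusted p of called lists that lost their call was for genotypes at day 11 distal tubule 0.0824, for averaged day 11 chemokine 0.0576.

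Without single libraries the number called ran from 0 to 3 for flox day 4 (3 without flox PBS 3, 1 without flox day 4 2), 0 to 3 for flox day 11 (3 without flox PBS 3), 0 to 10 for cKO day 4 (10 without cKO day 4 1), 3 to 10 for cKO day 11 (4 without cKO PBS 1, 3 without cKO PBS 2, 4 without cKO day 11 2), 0 to 2 for genotypes under PBS (2 without flox PBS 3), 0 to 14 for genotypes at day 4 (14 without cKO day 4 1), 0 to 1 for genotypes at day 11 (1 without flox day 11 3), 1 to 3 for genotypes on average (2 without flox PBS 3, 3 without cKO day 4 1), 0 to 4 for interaction at day 4 (4 without cKO day 4 1), 0 to 6 for day 11 against day 4 (6 without cKO day 4 1, 4 without flox day 11 1, 1 without cKO day 11 3), 2 to 16 for averaged day 4 (6 without flox PBS 3, 5 without cKO PBS 3, 12 without cKO day 4 1, 16 without cKO day 4 3).

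The podocyte list in flox day 4 (adjusted p = 0.0123) ranged from 0.00244 to 0.0709 and lost its call without flox PBS 1 (0.0505) and flox PBS 3 (0.0709). The mitochondrially encoded list in flox day 4 (adjusted p = 0.0246) ranged from 0.00750 to 0.0913 and lost its call without flox PBS 1 (0.0687), flox PBS 3 (0.0913), flox day 4 1 (0.0862) and flox day 4 2 (0.0544). The immediate early and heat shock list in flox day 4 (adjusted p = 0.0355) ranged from 0.0282 to 0.0709 and lost its call without flox PBS 1 (0.0693), flox PBS 2 (0.0532), flox PBS 3 (0.0709), flox day 4 2 (0.0606) and flox day 4 3 (0.0645). The podocyte list in flox day 11 (adjusted p = 0.0101) ranged from 4.26e-05 to 0.163 and lost its call without flox PBS 3 (0.121), flox day 11 2 (0.0981) and flox day 11 3 (0.163). The parietal epithelial list in flox day 11 (adjusted p = 0.0413) ranged from 0.00278 to 0.622 and lost its call without flox PBS 1 (0.0541), flox PBS 3 (0.622), flox day 11 2 (0.0694), flox day 11 3 (0.163) and flox day 11 4 (0.183). The proximal tubule list in flox day 11 (adjusted p = 0.000823) ranged from 5.56e-06 to 0.163 and lost its call without flox PBS 2 (0.0814) and flox day 11 3 (0.163). The immediate early and heat shock list in flox day 11 (adjusted p = 0.0378) ranged from 0.00218 to 0.183 and lost its call without flox PBS 1 (0.0669), flox PBS 2 (0.0814), flox PBS 3 (0.0680), flox day 11 2 (0.0626), flox day 11 3 (0.163) and flox day 11 4 (0.183). The monocyte and macrophage list in cKO day 4 (adjusted p = 0.00359) ranged from 0.00376 to 0.0834 and lost its call without cKO PBS 1 (0.0834). The mitochondrially encoded list in cKO day 4 (adjusted p = 0.00359) ranged from 0.000161 to 0.193 and lost its call without cKO PBS 1 (0.0834) and cKO day 4 3 (0.193). The immediate early and heat shock list in cKO day 4 (adjusted p = 0.0421) ranged from 0.0126 to 0.161 and lost its call without cKO PBS 1 (0.134), cKO PBS 3 (0.161), cKO day 4 1 (0.0917), cKO day 4 3 (0.0619) and cKO day 4 4 (0.111). The oxidative stress and Nrf2 list in cKO day 4 (adjusted p = 0.00276) ranged from 0.000954 to 0.193 and lost its call without cKO PBS 1 (0.0834) and cKO day 4 3 (0.193). The proximal tubule list in cKO day 11 (adjusted p = 0.000503) ranged from 3.78e-06 to 0.117 and lost its call without cKO PBS 3 (0.117). The oxidative phosphorylation list in genotypes at day 4 (adjusted p = 0.0210) ranged from 0.00214 to 0.410 and lost its call without flox day 4 2 (0.195), cKO day 4 2 (0.307) and cKO day 4 3 (0.410). The distal tubule and collecting duct list in genotypes at day 11 (adjusted p = 0.0330) ranged from 0.000532 to 0.712 and lost its call without flox day 11 1 (0.712), flox day 11 2 (0.132), cKO day 11 1 (0.133) and cKO day 11 2 (0.313). The monocyte and macrophage list in genotypes at day 11 (adjusted p = 0.00152) ranged from 0.000123 to 0.114 and lost its call without cKO day 11 2 (0.114). The erythrocyte list in genotypes at day 11 (adjusted p = 0.00152) ranged from 4.69e-05 to 0.266 and lost its call without flox day 11 1 (0.266). The extracellular matrix and fibrosis list in genotypes at day 11 (adjusted p = 0.0330) ranged from 0.00202 to 0.526 and lost its call without flox day 11 1 (0.266), flox day 11 2 (0.156), cKO day 11 2 (0.526) and cKO day 11 4 (0.262). The erythrocyte list in interaction at day 11 (adjusted p = 0.00146) ranged from 9.58e-06 to 0.0755 and lost its call without cKO PBS 1 (0.0596) and flox day 11 1 (0.0755). The monocyte and macrophage list in averaged day 4 (adjusted p = 0.0309) ranged from 0.0173 to 0.105 and lost its call without flox PBS 2 (0.0659), flox PBS 3 (0.105), cKO PBS 1 (0.0794), cKO PBS 3 (0.0511), flox day 4 3 (0.0600) and cKO day 4 2 (0.0715). The oxidative stress and Nrf2 list in averaged day 4 (adjusted p = 0.00981) ranged from 0.00251 to 0.164 and lost its call without flox PBS 3 (0.0562), cKO PBS 1 (0.0557) and cKO day 4 3 (0.164).

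Of values not called, Aldoc in genotypes under PBS, whose fitted fold is no bound since flox PBS had 0 reads, went to 0.0 without cKO PBS 3 (range 0.0 to 11.00). The sign turned without single libraries for Rapgef3 in genotypes at day 11 (−0.21, range −0.37 to 0.17), Rapgef4 in genotypes on average (0.11, range −0.17 to 0.45), Nphs1 in genotypes on average (−0.056, range −0.14 to 0.048), Podxl in genotypes on average (0.049, range −0.12 to 0.19) and Synpo in genotypes on average (−0.049, range −0.15 to 0.027). It turned with voom for Rapgef4 in genotypes on average (−0.18). The direction of the glycolysis test turned at day 4 between genotypes with no low-count filter (adjusted p = 0.995), the block (adjusted p = 0.967), without both libraries (0.887) and with detected genes (0.972), at day 11 without both libraries (0.896) and on average with no low-count filter (0.983). Without single libraries its adjusted p ran from 0.500 to 0.992 for genotypes under PBS, 0.891 to 0.993 for genotypes at day 4, 0.584 to 0.999 for genotypes at day 11, 0.847 to 0.9996 for genotypes on average and 0.487 to 0.997 for interaction at day 4. Counted over all lists followed here, leaving out a single library turned the direction of a list test in 17 cases. The correlation of the responses across genes moved from 0.046 to 0.19 at a mean log2 CPM of at least 5 and 0.50 at 8 at day 4, and from 0.053 to 0.18, 0.55 and, over the 7 genes called in either genotype, 0.96 at day 11. With the median over the list, the difference in tubule content turned to 0.10 for cKO day 4 against PBS and −0.14 between genotypes at day 11.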

Other observations

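Of the tests in this part, the one for testis RNA, the shares of splits for single lists and those of the comparisons averaged over genotypes against PBS were chosen after the result was seen.

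Several cell types gave no list call in any of the 13 comparisons. The smallest adjusted p was 0.21 for glomerular endothelial, 0.16 for mesangial and mural, 0.16 for neutrophil, 0.15 for T and NK cell and 0.16 for B and plasma cell genes, against 8.2e-08 for macrophage genes. By mean log2 CPM per library, the neutrophil list ran from −3.16 to 1.92 and the T and NK cell list from −2.80 to 1.41. The B and plasma cell list ran from −1.31 to 3.95 and the macrophage list from 1.30 to 4.94. Lists near the value for 0 reads (−3.16) could hardly show a change, so their missing calls do not show that those cells were unchanged. Among pathways the smallest was 0.053 for the interferon response, 0.18 for complement and coagulation, 0.18 for endoplasmic reticulum stress and 0.44 for cyclic AMP and Epac signalling. Platelet genes had too few tested members for a set test.

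Beside the respiratory chain, 3 further lists of metabolism and stress were called lower at day 11 than at day 4. The tricarboxylic acid cycle list was lower with 16 of 20 members below 0 (median −0.37, adjusted p = 0.00077, and adjusted p = 0.071 with an estimated correlation) as were the lists of fatty acid oxidation with 20 of 23 (median −0.53, adjusted p = 0.00077, and adjusted p = 0.064 with an estimated correlation) and of oxidative stress and Nrf2 with 18 of 24 (median −0.35, adjusted p = 0.00081, and adjusted p = 0.064 with an estimated correlation). With the proximal tubule covariate the first 2 lost their calls (adjusted p = 0.085 and 0.13). The erythrocyte list was called between these stages too (adjusted p = 0.0054), but its call was lost with an estimated correlation. In 12 of 100 splits, the real one counted in, its adjusted p was as small.

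Nipal1 and Prm1 marked the cKO libraries. Testis RNA is argued against, since Prm2 and Tnp1, protamine and transition protein genes named after their values were seen, had 0% of the 3809 Prm1 reads of the cKO libraries. A changed region around Nipal1 on chromosome 5 cannot be told apart from chance, because of the 15 tested genes within 1 Mb only 1, Cwh43 (4.36, named after its value was seen), had an unadjusted p under 0.05 (binomial p = 0.54) and so few neighbours decide nothing. A candidate explanation is sequence carried by the Cre transgene or its insertion site, which is confounded with the genotype and was not tested, and a biological effect of the Epac1 deletion stays open too.

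The mitochondrially encoded and oxidative phosphorylation lists were lower at day 11 than at day 4. Mitochondrial genes took on average 5.57% of reads under PBS, 7.68% at day 4 and 5.47% at day 11 in flox. In cKO the means were 6.39%, 7.77% and 3.90%. The oxidative phosphorylation list was called higher at day 4 than under PBS averaged over genotypes (adjusted p = 2.6e-06), though not with an estimated correlation. A rise at day 4 therefore stays open beside a fall at day 11. With a proximal tubule covariate the mitochondrially encoded list kept 61.2% of its median (−0.68 to −0.42, 11 of 13 members kept at least 50%, adjusted p = 1.2e-06) and the oxidative phosphorylation list 68.6%. The distal tubule list kept 82.3% (adjusted p = 5.8e-05). The covariate measures proximal tubule with error and leaves such other tubule in place. Less tubule in the day 11 libraries therefore stays open as a cause for these lists. The tricarboxylic acid cycle kept 30.02% (adjusted p = 0.085) and fatty acid oxidation 49.6% (adjusted p = 0.13), so tubule content stays open there too. One library as the cause is argued against, the highest adjusted p of the mitochondrially encoded list without each library being 5.8e-12. A change with the stage of nephritis is a hypothesis that remains. A difference in RNA quality or depth stays open as well, since the CT010467.1 share was 18.7% in flox and 17.5% in cKO at day 4 against 20.4% and 29.0% at day 11, and mean library totals, in units of 1e6 reads, were 20.4 and 18.5 against 17.6 and 12.4.

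The cell cycle list was higher at day 4 than under PBS in flox mice. With detected genes as a covariate the list stayed called (adjusted p = 1.1e-08). The groups did not overlap in detected genes, with 9777 to 10973 in flox PBS and 11068 to 12055 in flox day 4. The covariate is thus largely tied to the group, and few detected genes in the flox PBS libraries stay open as a cause. Members near the floor stay open, because the 16 members with a mean log2 CPM of at least 4 (median log2 fold change 1.94) were chosen on a mean that the rise itself lifts, and all 16 were higher. Proliferation in the nephritic glomerulus remains as a hypothesis, and the call was lost with an estimated correlation (adjusted p = 0.13).

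Other splits of the same libraries into groups of the same sizes showed how often as many genes arose, with no adjustment over the comparisons. The share of splits, the real one counted in, was under 5% for cKO day 11 against PBS (7 called, 1 of 35 splits as many, highest other 4), for day 11 against PBS averaged over genotypes (17 called, 1 of 100, highest other 3), for day 4 against PBS averaged over genotypes (3 called, 3 of 100, highest other 9, though not at an unadjusted p under 0.05 with 1290 genes, 5 of 100 and 1547) and, at an unadjusted p under 0.05, for day 11 against day 4 (1191 genes, 1 of 100, highest other 1185). Chance cannot be excluded for the number of genes in the averaged genotype comparison (1 called, 8 of 100, highest other 3, and 920 at an unadjusted p under 0.05, 49 of 100, highest other 1280). This number does not ask which gene was called, so it does not test Nipal1 itself. Nipal1 exceeded 20 CPM in 10 of 11 cKO libraries and 0 of 10 flox libraries. At an unadjusted p under 0.05 chance cannot be excluded for flox day 11 (1147 genes, 3 of 35, highest other 1187), cKO day 4 (1134, 4 of 35, 1666), the genotypes at day 4 (1031, 21 of 35, 1645) and day 11 (815, 24 of 35, 969), or the interactions at day 4 (1076, 18 of 100, 1614) and day 11 (964, 9 of 100, 1084). The 10 splits of flox day 4 (1102 genes, 1 as many, highest other 971) and of the genotypes under PBS (837, 2 as many, 874) are too few for a share under 5%. With DESeq2, refitted on the 13898 filtered genes where the counts of 670 and 531 calls used all genes, chance cannot be excluded for cKO day 11 (640 calls, 4 of 24 splits as many, highest other 685) or the genotypes at day 11 (495, 18 of 24, 574). These 24 were drawn from 35 to limit computing time, after all 35 had been seen.

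List calls arose often in other splits, so the adjusted p of a list can overstate the evidence. Splits that keep part of a real group difference can give calls as well, and these readings were not separated. The real split counted in, the matrix list was called in 49 and the cell cycle list in 55 of 100 splits for day 11 against PBS averaged over genotypes, the mitochondrially encoded list in 36 of 100 for day 11 against day 4, and the cell cycle list in 4 of 10 for flox day 4. The share of splits with an adjusted p as small was under 5% for 36 of 62 list calls in comparisons with enough splits. These were 10 of 13 for averaged day 11, 8 of 8 for averaged day 4, 8 of 9 for day 11 against day 4, 7 of 13 for cKO day 11, 2 of 7 for cKO day 4 and 1 of 6 for flox day 11. The lists were picked for their call in the real split, and the shares were not adjusted over the 62 calls. Of the averaged day 4 lists, none held with an estimated correlation. Chance is therefore not excluded for a single list. For averaged day 11 the matrix list had 8.5e-25 (smallest other 3.4e-13) and the cell cycle list 1.6e-19 (4.4e-19), for day 11 against day 4 the mitochondrially encoded list 5.0e-17 (6.8e-13), for cKO day 11 the matrix list 3.1e-22 (3.1e-19), and for flox day 11 the matrix list 1.3e-09 (2.4e-09). The share was 5% or more for the cell cycle list in flox day 11 (2 of 35 splits as small, smallest other 4.4e-16), for the cell cycle (3 of 35, 6.6e-07) and matrix lists (2 of 35, 0.00039) in cKO day 4, and for the podocyte (4 of 35, 2.8e-07), proximal tubule (5 of 35, 1.1e-06), macrophage (2 of 35, 1.1e-08), erythrocyte (2 of 35, 9.7e-11), distal tubule (2 of 35, 1.1e-08) and parietal cell activation and crescent lists (2 of 35, 0.00013) in cKO day 11. It was 5% or more as well for each list called between genotypes, at day 11 macrophage (3 of 35, 0.00045), erythrocyte (9 of 35, 1.2e-05), distal tubule (9 of 35, 1.6e-06) and matrix (10 of 35, 2.2e-06), at day 4 oxidative phosphorylation (8 of 35, 0.00071), and in the day 11 interaction erythrocyte (8 of 100, 2.8e-12). The 4 lists of flox day 4 had too few splits for a share under 5%, and the cell cycle list had 1.1e-11 there against 0.021 as the smallest other.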
